A study of Mus musculus with 4 samples.

How the data were processed

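The data are 4 single-cell RNA libraries of dissociated mouse gastric corpus epithelium, 1 each from untreated mice, mice at day 1 and at day 3 after L635, and mice at day 3 after L635 with AREG. Per the labels' protocols, the tissue was dissociated with TrypLE and the kinase inhibitor Y27632 for 5 min at 37 C, and 25000 cells were loaded per PIPseq T20 3' capture. The deposited values are raw counts of UMIs per gene and barcode, whole numbers that the authors left unfiltered and unnormalised, with 923384 to 1181916 barcodes per library. The genome build was mm39 (GRCm39) per the submitters' processing notes. The aligner and the counting program are not given in the sources used here. The reference at hand was of the older build, so gene names and identifiers are those of the deposited files and no coordinates are given. The files listed 32227 genes, with 27 repeats of a gene symbol; the first entry of each symbol was used.

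The design, the filters, the cell type markers, the gene lists and the rule for naming genes were fixed before the data were examined. A barcode was taken as a cell with at least 500 UMIs, at least 200 genes and at most 50% mitochondrial UMIs, a wide limit because parietal cells are rich in mitochondria. In the order untreated, day 1, day 3 and AREG, 15016, 4071, 8139 and 13121 barcodes had enough UMIs, 14460, 4047, 8076 and 13074 of these had enough genes, and 13897, 3926, 7986 and 12923 also met the mitochondrial limit. Scrublet, run per library in scanpy, marked 43, 0, 14 and 38 cells, which were removed. That is 0.309%, 0%, 0.175% and 0.294% of cells, far below the 0.8% per 1000 cells assumed for such captures, so the caller is taken not to have worked; the true doublet rate was not measured. Cells held 62.1%, 70.3%, 67.1% and 63.6% of each library's UMIs, and the deepest cell had 88112, 474828, 124195 and 76690 UMIs. Median genes per cell were 881, 1270, 1184 and 1081, and median mitochondrial shares 5.50%, 1.85%, 2.92% and 5.63%. Barcodes ranked 20001 to 200000 had a median of 97, 38, 49 and 74 UMIs, which measures free RNA.

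All 38637 cells were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes without mitochondrial, ribosomal protein and haemoglobin genes gave 40 principal components, and 15 neighbours and Leiden resolution 1 gave 25 clusters. A cluster took the name of the best of 20 marker classes if it had at least 3 detected markers of it among genes higher than elsewhere, at least 1 marker of it among its 50 leading genes, and no more markers of another class than of its own among the first 10. A cluster whose median UMIs were far below its library's stayed unnamed unless such markers led it. The markers were fixed in advance and the scoring was not. Its first form compared each cluster with all other cells and left clear parietal and pit clusters unnamed. It was replaced after the data were seen by a comparison with clusters of other classes. Unnamed epithelial cells were 0.0652%, 29.0%, 0.163% and 0.179% of the libraries, in the order above. In all, 38375 cells were epithelial. No cell annotation was used here, so classes are called pit-like, neck-like and so on.

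There was 1 library per group, so no test was run. The comparisons were day 1 with untreated, day 3 with day 1, and AREG with day 3, and day 3 with untreated was kept as a side comparison. Shares of epithelial cells carry exact Clopper-Pearson 95% intervals and their log2 ratios Katz intervals. Raw counts were summed over cells, scaled to CPM and compared as log2 ratios with a pseudocount of 1 CPM, which understates differences of low genes. Summed counts carry exact Poisson 95% intervals, and ratios of counts without a pseudocount carry conditional exact binomial ones. To judge whether an alternative moved the Areg ratio, that interval was shifted onto the value with the pseudocount. All intervals cover counting error only. Genes named were the 10 highest and 10 lowest log2 ratios in all epithelial cells, and the 5 highest and 5 lowest in each class with at least 100 cells in both libraries, among genes with at least 50 CPM in either library, without mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes or unnamed gene models. Members of the fixed lists could also be named. Of 23 such lists, members with at least 10 UMIs over both libraries were used, and a list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression. 3 listed genes were not in the files (Atp5f1a, Atp5f1b and Dpcr1). Shares of cells with at least 2 UMIs of a cycle list were taken after thinning every cell to 500 UMIs. The free RNA profile came from barcodes under 50 UMIs.

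The alternatives fixed before the data were examined were at least 1000 UMIs per cell, at most 20% mitochondrial UMIs or no such limit, doublets kept, Leiden resolutions of 0.5 and 2, a pseudocount of 10 CPM, CPM without mitochondrial, ribosomal protein and the 20 most abundant other genes, subtraction of the free RNA profile, equal weight for each cell and no filter on low counts. Alternatives chosen after seeing the data were the named epithelial cells as denominator, removal of the highest Scrublet scores at the expected rate, the deepest 1% of cells left out, and list medians without the abundant genes. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.

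The computations were tested on simulated data. Counts were drawn for all genes of the 3 comparisons. Among 1881, 2182 and 2137 genes with at least 50 CPM, 100 were set at 2-fold and 100 at 4-fold. In each comparison 100% of either fold size came back among the 200 largest ratios of these genes. The counts had Poisson noise only, without differences between animals or libraries. At such depth full recovery was foreseeable, so it and the interval coverage test the computation alone. Intervals held the true ratio for 95.0%, 92.5% and 95.0% of genes, a planted list of 12 genes lay at percentile 100 and an unaltered list at 4.02, 90.9 and 31.3. Of 300 simulated cells per class, 99.7% of pit, 98.7% of neck, 100% of chief, 98.7% of parietal and 98.0% of proliferating cells were named as drawn. These cells were drawn from the summed untreated profiles of the classes that the same naming had made. They had no doublets, added free RNA or injured cells, so they test the computation and not the naming of real cells.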

Results

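RNA was measured in single cells of the mouse gastric corpus, the acid-secreting body of the stomach, with the PIPseq T20 3' method. The animals were C57BL6/J mice aged 6 to 7 weeks. L635, a compound that is toxic to the acid-secreting parietal cells, was given once by mouth at 350 mg/kg. The 4 groups were untreated mice, which received PBS, mice at day 1 after L635, mice at day 3 after L635, and mice at day 3 that also received AREG. AREG (amphiregulin) is a ligand of the epidermal growth factor receptor, EGFR. Its dose, route and schedule are not given in the sources used here. There was 1 library per group, so no difference below has a replicate check, no test was possible and no p-value is given.

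The untreated library held 98893436 UMIs (counted RNA molecules), day 1 held 56007532, day 3 held 62591649 and the AREG library held 81286332. Cells that passed the filters numbered 13854, 3926, 7972 and 12885 in the same order, and 13797, 3738, 7965 and 12875 of them were epithelial. Median UMIs per cell were 2503.5, 2724.5, 3013 and 2684. Intervals in parentheses are 95% confidence intervals, exact Clopper-Pearson for shares of cells and exact Poisson for CPM (counts in summed cells, scaled to 1e6 in all), and they cover counting error only. Log2 ratios of expression are of CPM + 1.

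Day 1 was compared with the untreated library to describe the acute injury. The acid pump genes Atp4a and Atp4b and the chief cell enzyme genes Pla2g1b and Chia1 were lower at day 1, and so were the shares of parietal-like and chief-like cells. Areg and other EGFR ligand genes, genes of DNA replication such as Mcm4 and Rrm2, and genes of wounded or metaplastic epithelium such as Sprr1a, Krt7 and Cd44 were higher. The proliferating-like share was higher as well.

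Parietal-like cells were 31.4% of epithelial cells in the untreated library (30.6 to 32.2) and 8.19% at day 1 (7.33 to 9.11), a log2 ratio of -1.94 (-2.10 to -1.78), which was -4.00 with at most 20% mitochondrial UMIs per cell. Proliferating-like cells were 8.28% (7.83 to 8.76), from 1143 cells, and 29.9% (28.4 to 31.4), from 1117 cells. The higher share thus went with fewer epithelial cells in all, 13797 and 3738, and not with more proliferating-like cells in the library. The log2 ratio of the shares was 1.85, or 3.61-fold. That ratio was 0.91 with at most 20% mitochondrial UMIs, 1.11 without the highest Scrublet scores, and -2.75 at Leiden resolution 0.5, where 81.7% of day 1 epithelial cells were unnamed. Pit-like cells, the mucous cells of the surface, were 34.4% (33.6 to 35.2) and 28.4% (26.9 to 29.8), a log2 ratio of -0.28 (-0.36 to -0.20). That direction depended on 1084 shallow day 1 cells of cluster 11, 29.0% of the day 1 epithelial cells, which stayed unnamed; without unnamed cells the pit-like log2 ratio was 0.21. Neck-like cells, which make Muc6 mucin, were 14.1% and 2.11%, and chief-like cells, which make pepsinogen, were 7.98% and 0.161%, the latter from 6 cells (8.13% and 0.0268% at Leiden resolution 0.5). Different clusters held the classes in the 2 libraries. The untreated parietal-like cells lay in clusters 2 and 15, the pit-like cells in clusters 4 and 6 and the proliferating-like cells in cluster 7. At day 1, 83.7% of parietal-like cells lay in cluster 19, 87.2% of pit-like cells in cluster 13 and 93.4% of proliferating-like cells in cluster 12. These clusters were made almost wholly of day 1 cells and may be that library rather than a type, and cluster 12 was led by Msln, Krt7, Plac9, S100a10 and Sprr1a before Cdk1 and Tubb5.

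**Figure D1:**
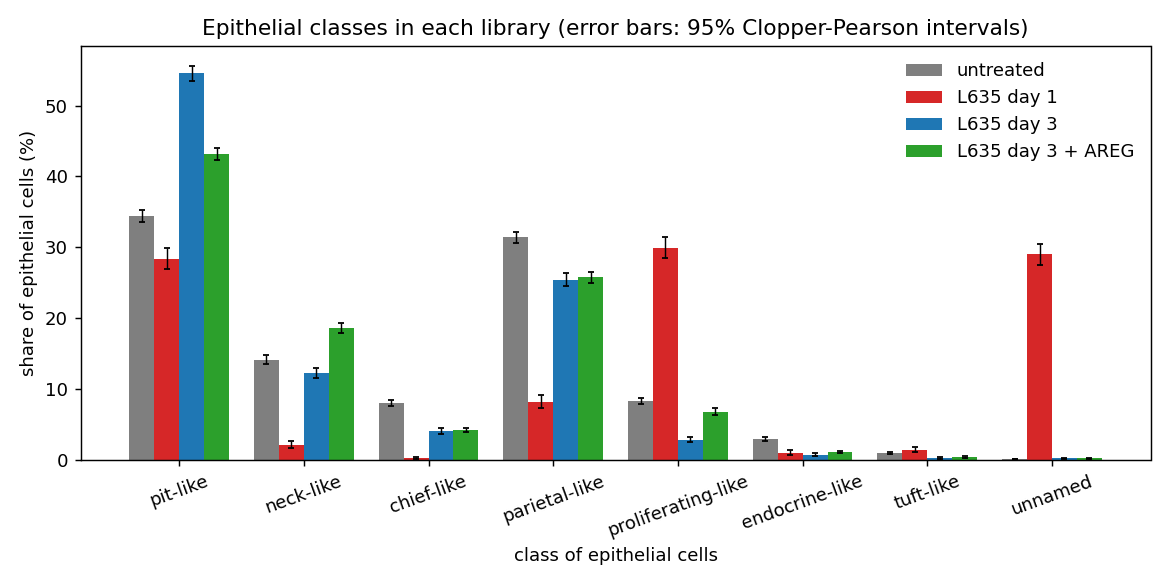
Share of epithelial cells (%) in each class for the 4 libraries, with 95% Clopper-Pearson intervals as error bars. The proliferating-like bar is highest at day 1 (29.9%) and lowest at day 3 (2.76%), and the pit-like bar is highest at day 3 (54.6%).

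Cycle genes were also counted without clusters, in cells thinned to 500 UMIs, which left no cell out; thinned shares were highest at day 1 and lowest at day 3. The share of epithelial cells with at least 2 UMIs of the G2/M genes, such as Mki67 and Top2a, was 2.45% in the untreated library, 7.09% at day 1, 1.39% at day 3 and 3.59% with AREG; unthinned it was 10.9%, 28.1%, 6.29% and 11.03%. For S-phase genes, such as Mcm4 and Pcna, the thinned shares were 2.83%, 9.87%, 1.19% and 1.55%, and the unthinned ones 20.9%, 49.0%, 19.5% and 17.9%. As background, parietal-like cells, which do not divide, gave G2/M shares of 0.531%, 0.980%, 1.04% and 0.694% and S-phase shares of 0.785%, 2.61%, 0.840% and 0.905%. Their median UMIs were 1867, 4794.5, 4077.5 and 3494. Within the proliferating-like class the thinned G2/M share was 20.4% in the untreated library and 14.7% at day 1, and the S-phase share 15.2% and 21.8%.

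Areg (ENSMUSG00000029378) was at 6.47 CPM in untreated epithelial cells (5.85 to 7.14) and at 80.4 CPM at day 1 (77.6 to 83.3), a log2 ratio of 3.45. The proliferating-like class held 78.8% of the day 1 Areg UMIs, at 122 CPM (117 to 127). It also held 20097614 of the 38638628 UMIs of all genes in day 1 epithelial cells. Day 1 pit-like cells had 31.8 CPM of Areg, parietal-like cells 39.7 and the unnamed cells 84.8. The parietal-like value rested on 120 UMIs, 25% of them in 1 cell. Hbegf was at 19.0 CPM and 54.1 CPM, Tgfa at 9.28 and 26.3, and Btc at 7.30 and 22.1. Ereg was scarce, at 0.0326 and 1.27 CPM, and Epgn was at 0.0978 and 0.181 CPM. Egf, whose untreated source was chiefly parietal-like cells with 25.4 CPM, went the other way, at 6.21 and 0.776 CPM. The receptor genes Egfr (6.78 and 14.6 CPM), Erbb2 (15.1 and 38.4 CPM) and Erbb3 (20.6 and 56.1 CPM) were higher at day 1.

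**Figure D2:**
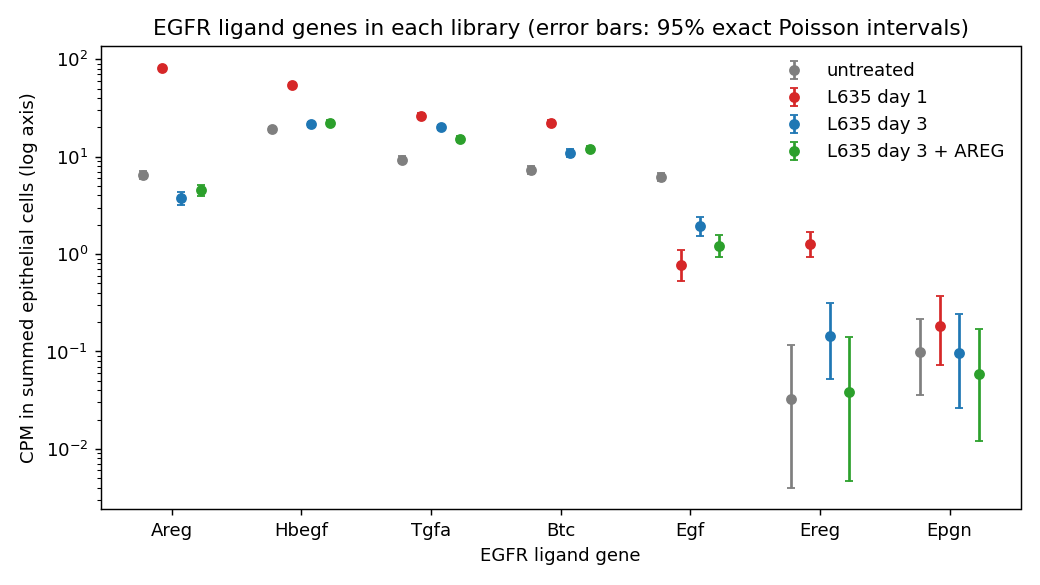
CPM of 7 EGFR ligand genes in summed epithelial cells of each library, on a log axis, with 95% exact Poisson intervals. Areg is at 80.4 CPM at day 1 and at or under 6.47 CPM in the other libraries, and Egf is highest in the untreated library.

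Among all epithelial cells the 10 highest log2 ratios at day 1 were those of Gast, Msln, Sprr1a, Krt7, S100a6, Lgals3, Plaur, S100a10, Areg and Obp2a. Sprr1a, a precursor of the cornified envelope, was at 485 CPM against 5.90, and Krt7, a keratin of simple epithelia, at 335 against 10.1. Msln, which encodes the surface protein mesothelin, was at 114 against 0.147 CPM. S100a6, a calcium-binding protein gene, was at 13887 against 516 CPM, and its relative S100a10, the partner of annexin A2, at 117 against 8.77. Lgals3 (galectin-3, a sugar-binding lectin) was at 527 against 27.6 CPM, Plaur (the urokinase receptor, used in matrix remodelling) at 77.6 against 4.73, and Obp2a (a lipocalin) at 92.3 against 9.29. Gast, the gastrin gene of antral endocrine cells, had 4245 UMIs at day 1, 48.9% of them in 1 cell, and 1 UMI in the untreated library, so its log2 ratio is between 10.24 and 18.02. Among the lowest log2 ratios were those of the digestive enzyme and chief cell genes Try4 (1.32 against 142 CPM), Pnliprp1 (1.99 against 149), Chia1 (108 against 3918), Pla2g1b (1078 against 38089), Pga5 (29.3 against 665), Cblif (106 against 1768) and Clps (2960 against 46420). Chia1 encodes an acidic chitinase, Pla2g1b a secreted phospholipase, Pga5 a pepsinogen, Cblif gastric intrinsic factor and Clps colipase.

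Within parietal-like cells Sprr1a was at 1635 CPM at day 1 against 2.61, S100a6 at 4041 against 63.9 and Lgals3 at 186 against 4.43. Gclc, which limits glutathione synthesis, was at 857 against 25.7 CPM there, and Akr1b8, an aldo-keto reductase gene, at 465 against 18.9. Pit-like cells had more Fkbp5, a glucocorticoid-induced chaperone gene (171 against 4.96 CPM), and less Il33, an epithelial alarm cytokine (4.15 against 58.1 CPM). These 2 sets of pit-like cells differed in depth, with median UMIs of 7970.5 at day 1 and 2641.5 in the untreated library. Shallow day 1 cells stayed unnamed in cluster 11. Pla2g1b led the lower genes of pit-like cells, at 49.6 against 1830 CPM, and free RNA as measured in empty barcodes amounted to 1182 CPM of the untreated value. Chia1 (2.18 against 106 CPM) and Clps (242 against 2903 CPM) followed. In proliferating-like cells Msln had 185 CPM against 3 UMIs in the untreated library, a log2 ratio between 7.71 and 11.54. Krt7 (519 against 5.84) and Nupr1, a stress-response gene (315 against 5.84), were higher there too. Sectm1b (2.59 against 67.8 CPM) and Mogat1, a gene of glyceride synthesis (37.6 against 430), were lower.

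For the fixed gene lists, the reference is the median log2 ratio of all measured genes, which was 0.32, or 0.13 once mitochondrial, ribosomal protein and the 20 most abundant other genes were left out, so each list median is followed by its distance from 0.32. Wound repair and migration genes had a median of 1.42 (1.10 from the all-gene median), with 12 of 13 higher. The EGFR ligand list had a median of 1.41 (1.09), ERK response genes 1.30 (0.99), ERBB receptors and regulators 1.13 (0.81), S-phase genes 1.22 (0.90) and SPEM and metaplasia genes 1.15 (0.83). Members included Fosl1, an AP-1 factor downstream of ERK (10.97 against 0.685 CPM), Epha2 (38.2 against 6.49), Cd44 (19.6 against 1.53), Wfdc2 (242 against 53.5) and Clu (5290 against 2000). Dusp6, an ERK phosphatase gene, was the 1 ERK list member that was lower (8.90 against 15.8 CPM). Mcm4, part of the replicative helicase, was at 30.8 against 8.31 CPM, and Rrm2, which makes deoxynucleotides, at 67.1 against 16.4. On the lower side were lists for chief cells at -1.53 (-1.85), parietal cells at -1.37 (-1.69), gastrointestinal hormones at -1.37 (-1.68), the interferon response at -0.49 (-0.81), neck cells at -0.46 (-0.78), oxidative phosphorylation at -0.30 (-0.62) and MHC class II at -0.22 (-0.54). Atp4a was at 889 against 2920 CPM and Atp4b at 441 against 2851. Endocrine-like cells, which make the hormones, were 0.936% at day 1 and 2.84% in the untreated library, and single cells held 60.3% of the Sst and 47.3% of the Ghrl UMIs at day 1. The MHC class II median was that of H2-DMb1, with 80 against 158 UMIs and an interval of -0.72 to 0.08, and H2-DMa was higher (3.18 against 2.09 CPM). With a pseudocount of 10 CPM the chief cell median was -0.57 and the ERK response median 0.61, and with no filter on low counts the hormone median was -0.61. These 13 lists lay outside the central 95% of matched random lists, but ERBB receptors came inside without the filter on low counts (percentile 97.4), and neck cell genes without the abundant genes (2.98). The other lists lay inside it, namely p53 and apoptosis at 0.78, hedgehog, BMP and Wnt signals at 0.75, immediate early genes at 0.70, stem and progenitor genes at 0.64, G2/M genes at 0.90, paligenosis genes at 0.54, glycolysis at 0.40 and pit cell genes at 0.37. Of these, pit cell genes lay outside without the abundant genes (percentile 98.2), and hedgehog, BMP and Wnt signals with a pseudocount of 10 CPM (99.6). Epithelial inflammation at 0.14 and the unfolded protein response at 0.13 also lay inside, and both turned negative (-0.06 and -0.21) without the abundant genes. All values of this comparison are differences between 2 libraries of unlike composition, and the 20 most abundant genes took 42.2% of UMIs in untreated and 27.1% in day 1 epithelial cells.

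**Figure D3:**
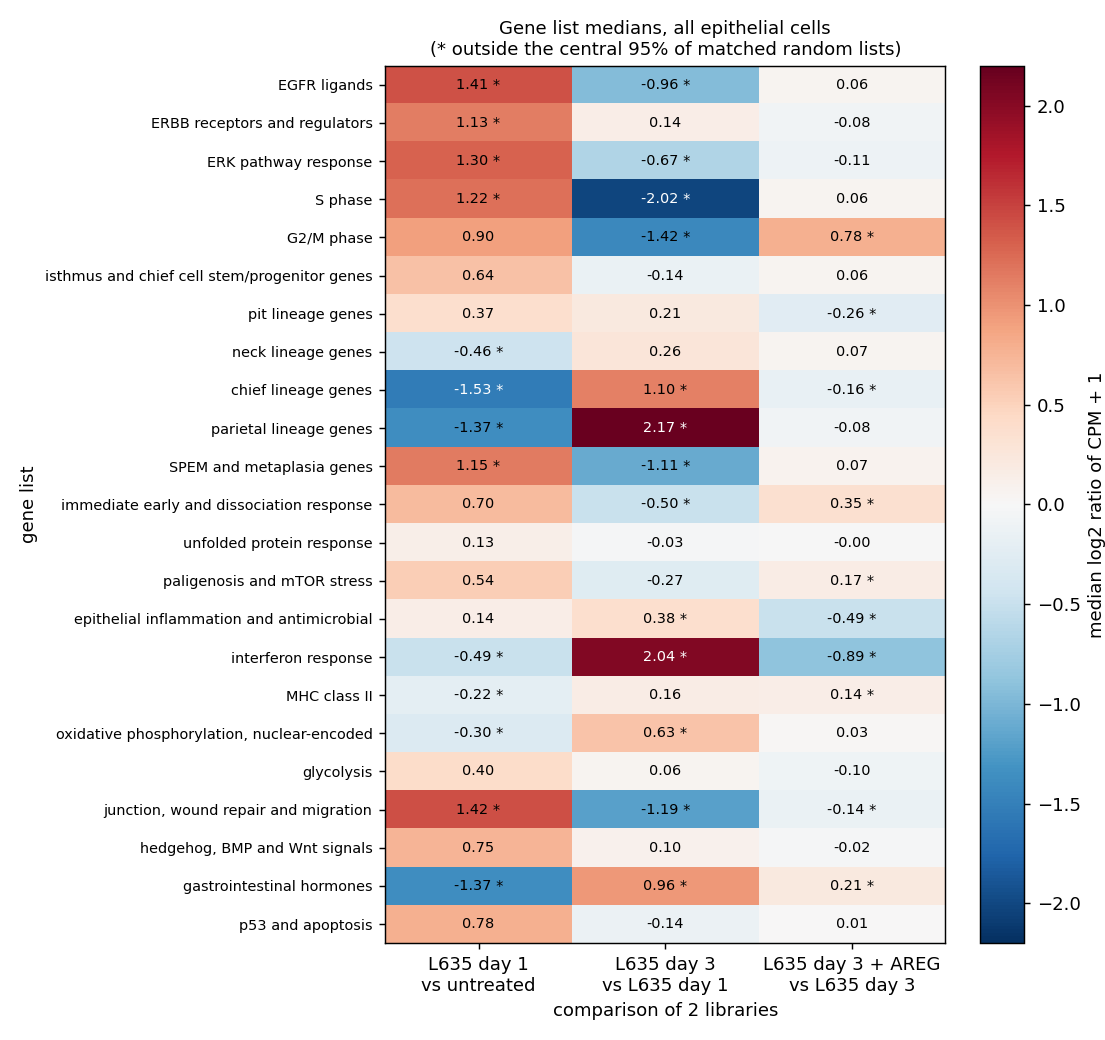
Median log2 ratio of CPM + 1 for each of 23 gene lists (vertical axis) in the 3 comparisons (horizontal axis), in summed epithelial cells, with a star where the median lies outside the central 95% of matched random lists. The S-phase list is at 1.22 for day 1 against untreated and at -2.02 for day 3 against day 1, and the G2/M list is at 0.78 for AREG against day 3.

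Day 3 was compared with day 1 to describe the early recovery. Acid secretion genes such as Atp4b and Kcne2 and the chief cell genes Chia1 and Pla2g1b were higher at day 3, while Areg, S-phase genes such as Mcm5 and the injury genes Sprr1a, S100a6 and Krt7 were lower. Interferon-stimulated genes such as Oasl2, Isg15 and Ifit1, which answer viral or inflammatory signals, were higher. Pit-like and parietal-like shares were higher and the proliferating-like share lower.

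At day 3 pit-like cells were 54.6% of epithelial cells (53.5 to 55.7), a log2 ratio to day 1 of 0.94 (0.87 to 1.02). Parietal-like cells were 25.4%, a log2 ratio of 1.63 (1.47 to 1.80), and proliferating-like cells 2.76% (2.41 to 3.15), a log2 ratio of -3.44 (-3.64 to -3.23). Leiden resolution 0.5 gave 0.27 for proliferating-like and 3.86 for pit-like cells, and at most 20% mitochondrial UMIs gave 3.69 for parietal-like cells. Neck-like cells were 12.2% and chief-like cells 4.04%, the latter 0.477% at Leiden resolution 0.5. Most day 3 pit-like cells lay in clusters 0 and 1, and others in cluster 16, which was led by the interferon genes Isg15, Oasl2, Ifit1 and Irf7. Day 3 parietal-like cells lay in clusters 5, 9 and 17 and proliferating-like cells in cluster 7, so these classes came mainly from other clusters than at day 1. Neck-like cells lay mainly in cluster 3 and chief-like cells in cluster 14 on both days, whereas 96.3% of untreated neck-like cells lay in cluster 8.

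Areg was at 3.74 CPM at day 3 (3.18 to 4.37), a log2 ratio to day 1 of -4.10, and at 7.31 CPM in pit-like cells. Hbegf was at 21.4 CPM, Tgfa at 19.9, Btc at 10.9 and Egf at 1.93, whereas Erbb2 at 36.3 CPM and Erbb3 at 46.9 stayed above their untreated levels. The highest log2 ratios at day 3 were those of Try4 (130 against 1.32 CPM), Tafa2 (106 against 2.74), Chia1 (2832 against 108), Oasl2 (53.4 against 1.84), Pnliprp2 (198 against 14.0), Kcne2 (252 against 18.3) and Atp4b (5046 against 441). Kcne2 encodes a subunit of the potassium channel that the acid pump needs, and Atp4b the pump's beta subunit. Pla2g1b (11083 against 1078 CPM), Slc5a5 (the iodide transporter, 172 against 16.8) and Gkn3 (a gastrokine of neck cells, 596 against 60.9) came next. Tafa2 was far higher in near-empty barcodes than in cells, and the level in cells divided the libraries into untreated and day 3 (49.5 and 106 CPM) against day 1 and AREG (2.74 and 2.98 CPM). The lowest log2 ratios were those of Sprr1a (2.88 against 485 CPM), Gast, Msln (0.405 against 114), S100a10 (1.31 against 117), S100a6 (399 against 13887), Obp2a (1.84 against 92.3), Plac9 (10.4 against 311), Lgals3 (29.4 against 527), Areg and Krt7 (19.6 against 335). Gast had 3 UMIs at day 3, and its log2 ratio is between -12.86 and -9.04.

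Pit-like cells had more RNA of the interferon genes Isg15 and Oasl2 at day 3. Isg15, a ubiquitin-like protein made in response to interferon, was there at 67.8 CPM against 1 UMI at day 1, a log2 ratio between 7.38 and 15.17. Oasl2, an antiviral sensor gene, was there at 114 against 1.02 CPM. Lower in pit-like cells were Sprr1a (5.37 against 158 CPM) and Plac9 (7.77 against 189). In parietal-like cells Aqp4, a water channel of these cells, was at 55.6 against 1.98 CPM. Ghrl was also among their highest genes, but 92.4% of its day 3 UMIs came from 1 cell. Sprr1a (0.651 against 1635 CPM), Obp2a (4.82 against 949) and S100a6 (39.2 against 4041) were lower there.

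Parietal cell genes had a median log2 ratio of 2.17, interferon response genes 2.04, chief cell genes 1.10, gastrointestinal hormones 0.96, oxidative phosphorylation 0.63 and epithelial inflammation 0.38. The hormone median lies midway between Gcg, with 14 against 4 UMIs, and Chga (348 against 111 CPM), and was 0.23 with no filter on low counts. Endocrine-like cells were 0.653% at day 3 and 0.936% at day 1, a log2 ratio of -0.52 (-1.14 to 0.10). The median gene of the inflammation list, Nos2, had 21 against 6 UMIs, 4 of its 7 genes were higher, and it lay inside the central 95% with a pseudocount of 10 CPM (percentile 86.0) or no filter on low counts (61.0). All 12 measured interferon genes were higher, including Ifit1 (17.9 against 0.181 CPM). S-phase genes had a median of -2.02 and G2/M genes of -1.42, and none of their 18 and 19 members was higher. Mcm5 was at 7.10 against 47.8 CPM and Hells, a chromatin remodeller of dividing cells, at 3.24 against 26.8. Wound repair genes had a median of -1.19, SPEM and metaplasia genes -1.11, EGFR ligands -0.96, ERK response genes -0.67 and immediate early genes -0.50. These 13 lists lay outside the central 95% of matched random lists. With a pseudocount of 10 CPM the medians were 0.54 for interferon response genes, -1.41 for S phase, -0.37 for wound repair and -0.28 for EGFR ligands. Inside it lay neck cell genes at 0.26 (outside it without the abundant genes, percentile 98.7), pit cell genes at 0.21, MHC class II at 0.16, ERBB receptors and regulators at 0.14, hedgehog, BMP and Wnt signals at 0.10, glycolysis at 0.06, the unfolded protein response at -0.03, stem and progenitor genes at -0.14, p53 and apoptosis at -0.14 and paligenosis genes at -0.27. Day 1 and day 3 animals differ in time since injury and in nothing else that the labels give, but the 1 library of each leaves animal and library differences inside every value.

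The AREG library was compared with day 3 without AREG to ask what an added EGFR ligand does during recovery. Mitosis genes were higher with AREG, among them Ube2c, which tags mitotic proteins for destruction, and Ccnb2, a mitotic cyclin, and the proliferating-like share was higher. Neck-like cells were a larger share but had less RNA of the neck cell genes Muc6, Gkn3 and Agr2, more of Tff2, and more Tff1 and Muc5ac, which are pit cell genes. Interferon genes such as Isg15 and the oxidase gene Duox2 were lower. Areg RNA itself was close in both libraries.

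Proliferating-like cells were 6.77% of epithelial cells with AREG (6.34 to 7.22) and 2.76% without, a log2 ratio of 1.29 or 2.45-fold. Neck-like cells were 18.6% and 12.2%, a log2 ratio of 0.61 (0.51 to 0.71). Pit-like cells were 43.2% (42.3 to 44.1) and 54.6%, a log2 ratio of -0.34 (-0.38 to -0.30). Parietal-like cells were 25.7% and 25.4%, a log2 ratio of 0.02 (-0.05 to 0.09), and chief-like cells 4.16% and 4.04%. At Leiden resolution 0.5 the chief-like shares were 0.272% and 0.477%, so their near-equality depends on the clustering. In both libraries cluster 7 held most proliferating-like cells, cluster 3 most neck-like cells, cluster 14 most chief-like cells and cluster 5 most parietal-like cells. Pit-like cells differed, with 55.7% in cluster 0, 27.4% in cluster 1 and 2.97% in the interferon cluster 16 with AREG, against 36.1%, 45.9% and 7.64% without. Areg was at 4.51 CPM with AREG (3.95 to 5.13), a log2 ratio of 0.22, and with each cell given equal weight the ratio was -0.02. Hbegf was at 22.4 CPM, Btc at 12.02 and Egf at 1.22, and Tgfa was lower, at 15.1 against 19.9 CPM.

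The 10 highest log2 ratios with AREG were those of Cul3 (188 against 49.8 CPM), Ube2c (77.5 against 38.2), Tff2 (5877 against 3506), Hmgb2 (165 against 99.9), Spp1 (391 against 243), Fos (415 against 260), Zfp36 (81.1 against 50.9), Tuba1b (94.5 against 61.3), Tubb5 (109.5 against 72.6) and Mgst1 (70.1 against 47.3). Tff2 encodes the trefoil peptide of neck cells, Hmgb2 a chromatin protein of dividing cells, Spp1 osteopontin, Tuba1b and Tubb5 tubulins, and Fos and Zfp36 belong to the immediate early response that dissociation also induces. Cul3, a ubiquitin ligase scaffold gene, was at 24.9 CPM in the untreated library and 207 at day 1, so it divided the libraries as Tafa2 did, the other way round. All 3 comparisons cross that division. Mki67, a marker of cycling cells, followed the same pairs with 10.3 CPM in the untreated library, 35.4 at day 1, 11.5 at day 3 and 22.6 with AREG. The 10 lowest were Tafa2, Duox2 (39.6 against 100.2 CPM), Oasl2 (24.4 against 53.4), Gkn3 (286 against 596), Stk3 (55.5 against 114), Taco1 (49.8 against 102), Chia1 (1430 against 2832), Muc6 (117 against 229), Gpatch11 (46.7 against 89.0) and Gsta2 (203 against 357). Duox2 makes hydrogen peroxide at mucosal surfaces, Stk3 encodes a Hippo pathway kinase, Taco1 a factor for mitochondrial translation and Gsta2 a glutathione transferase.

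In neck-like cells Gkn3 was at 1314 CPM with AREG against 4153, Taco1 at 41.4 against 129, Muc6 at 643 against 1862 and the transcription factor gene Nfib at 145 against 379. Among other neck cell genes, Agr2 (3231 against 4949 CPM), A4gnt (99.2 against 151) and Spdef (133 against 159) were lower there, Tff2 was higher (13023 against 8518) and Creb3l4 level (175.0 against 174.7). S100a6 was at 299.6 against 90.8 CPM in these cells, Tff1 at 11351 against 4830, Gsta3 at 82.7 against 35.1 and Muc5ac at 413 against 182. Untreated neck-like cells had Tff1 at 8343 and Tff2 at 15733 CPM, both above day 3 without AREG, and Muc5ac at 84.2 CPM, below it. The neck cell list had a median of -0.43 within neck-like cells and the pit cell list 0.51. In pit-like cells the next gene after Cul3 was Tfrc, the transferrin receptor gene that growing cells use for iron uptake, at 68.0 against 26.1 CPM. Isg15 was lower in them, at 21.8 against 67.8 CPM. Proliferating-like cells had more S100a6 (807 against 328 CPM), Sox21 (50.7 against 21.4), Ccar1 (56.4 against 26.6) and Sgk1, a growth factor-responsive kinase gene (81.7 against 42.1), and less Ifitm3 (13.02 against 59.5), Gkn3 (263 against 1013) and Cblif (201 against 601). Within that class the thinned G2/M share was 43.7% with AREG and 32.7% without, and the S-phase share 6.88% and 14.5%. Among chief-like cells the day 3 levels of Sst, Ghrl, Amy2a2 and Amy2a3 rested on single cells, which held 92.7% of the Sst UMIs and 96.9% of the Ghrl UMIs, and the amylase copies are too alike to be told apart with certainty.

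All 19 measured G2/M genes were higher with AREG, with a median log2 ratio of 0.78, and they included Ccnb2 (27.5 against 11.3 CPM) and Cenpf, a kinetochore gene (8.03 against 3.29). S-phase genes had a median of 0.06. Immediate early genes had a median of 0.35, including Egr1 (197 against 142 CPM), gastrointestinal hormones 0.21, paligenosis genes 0.17 and MHC class II 0.14. The AREG library also had a higher median mitochondrial share, 5.63% against 2.92%, and more UMIs per empty barcode, 74 against 49. The hormone median was that of Gcg, with 28 against 14 UMIs, while Chga was at 460 against 348 CPM. Endocrine-like cells were 1.03% with AREG and 0.653% without, a log2 ratio of 0.65 (0.19 to 1.11). The MHC class II median was that of H2-Aa, with 8 against 2 UMIs, while Cd74 was lower (2.56 against 3.38 CPM), and the list lay inside the central 95% with a pseudocount of 10 CPM (percentile 96.9). Interferon response genes had a median of -0.89, with Ifit1 at 3.76 against 17.9 CPM, epithelial inflammation -0.49, pit cell genes -0.26, chief cell genes -0.16 and wound repair genes -0.14. These lists, apart from S phase, lay outside the central 95% of matched random lists, but wound repair genes came inside without the abundant genes (percentile 4.30), and epithelial inflammation lay on its edge without the filter on low counts (median -0.07). The others lay inside it, namely SPEM and metaplasia genes at 0.07, stem and progenitor genes at 0.06, oxidative phosphorylation at 0.03, p53 and apoptosis at 0.01, hedgehog, BMP and Wnt signals at -0.02, parietal cell genes at -0.08, ERBB receptors and regulators at -0.08, glycolysis at -0.10 and ERK response genes at -0.11. Neck cell genes at 0.07, EGFR ligands at 0.06 and the unfolded protein response at -0.00 had no settled direction, with -0.01, -0.05 and 0.01 under another setting each. AREG, library and animal cannot be separated with 1 library on each side.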

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

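The tests of explanations in this part were all chosen after the result they bear on was seen. The log2 ratios and list medians of the first paragraph come from the planned and side comparisons. Exceptions are the value with named cells as denominator, chosen after seeing the data, and the shares of cells outside the epithelial set. Several measures stood on opposite sides of the untreated library at day 1 and at day 3, and the difference between the days was not tested. The pit-like share had a log2 ratio to untreated of -0.28 at day 1 and 0.66 at day 3, but the day 1 value was 0.21 with named cells as denominator and 0.36 with at least 1000 UMIs, which puts both days on one side. The proliferating-like share had ratios of 1.85 and -1.58, with -2.75 at day 1 under Leiden resolution 0.5, and Areg had 3.45 and -0.66. The S-phase list, with Mcm4 and Rrm2, had medians of 1.22 and -0.69, and the interferon list, with Isg15 and Ifit1, had -0.49 and 1.60. Among cells outside the epithelial set, cluster 22 held 154 cells at day 1, 3.92% of that library's cells (3.34 to 4.58), and 0 in the untreated library, where the upper 95% bound is 0.0266%. Its leading genes included Nbea, St6galnac3, Lsamp and Notum, and it stayed unnamed and came from 1 library. Cluster 23, led by the endothelial genes Plvap and Fabp4, held 29 cells at day 1 (0.739%) against 0.137% in the untreated library.

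Tafa2, Gm50024, Cul3, Gm47854 and Cbfa2t2 divided the libraries into untreated with day 3 and day 1 with AREG, a division crossed by each comparison of the report; these genes were chosen after their values were seen. In barcodes under 50 UMIs, Tafa2 was at 1138 and 4616 CPM in the untreated and day 3 libraries against 7.12 and 4.93, and Gm47854 at 11247 and 5300 CPM in the day 1 and AREG libraries against 0.297 and 0.248. In the libraries that carry the mark, the level in cells was at most 0.127 times that in those barcodes. That ratio cannot exclude expression by the called epithelial cells. The median empty barcode held 1.39% to 3.87% of the UMIs of the median cell, a small part of all its UMIs. The marks were far denser in near-empty barcodes than in cells, so such barcodes can supply a larger part of them. Cbfa2t2 was at 1152 CPM in barcodes under 50 UMIs and 23.4 CPM in epithelial cells of the AREG library. How much of each mark in cells came this way was not computed. Free RNA is argued against, since the level in barcodes of 1 to 9 UMIs was at least 12.2 times that in barcodes of 200 to under 500 UMIs. Pgc kept 0.838 to 0.946. A batch of library preparation or sequencing that pairs the libraries stays open, because the labels give no batch and 1 library per group cannot exclude one; 0 other genes of epithelial cells lay over 2-fold apart between these pairs, against 14 and 2 in barcodes under 50 UMIs, where the pairing of day 1 with day 3 gave 10 and 0 and that of untreated with day 1 gave 27 and 78. In epithelial cells untreated and day 1 were both over 2-fold higher than both day 3 libraries for 23 genes and lower for 77. Day 3 against day 1 and day 3 against untreated cross that division, where a batch cannot be told apart from the time after L635. A shared biology of day 1 and AREG was not tested.

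Cluster 11, the shallow unnamed cells of the day 1 library, had a median of 776 UMIs and was led by Cym, Lgals3, S100a6, Krt7 and Sprr1a. Next came Cbfa2t2 and Gm47854, which mark the near-empty barcodes of this library. Gm47854 was at 756 CPM, against 408 and 381 in the proliferating-like and pit-like day 1 clusters and 11247 in barcodes under 50 UMIs. Empty barcodes with free RNA alone are argued against chiefly by Atp4a, at 120 CPM against 876 in barcodes under 50 UMIs, a ratio of 0.137. Gm47854 was lower too but cannot decide, since it fell with depth, to 1375 CPM in day 1 barcodes of 200 to under 500 UMIs. Cym was higher (993 against 138 CPM), but 10 cells held 91.3% of its UMIs. Other genes lay near the level of barcodes under 50 UMIs, such as Tff1 (85845 against 71565 CPM), Pgc (18092 against 17076) and Krt7 (397 against 315). These genes do not tell the cluster from those barcodes. Gkn2 (52872 against 33334) and Lgals3 (742 against 463) were further above it. Shallow cells of the proliferating-like and pit-like day 1 clusters stay open, because the spread of the Tff1, Gkn1 and Gkn2 share per cell was 1.02 times that of a mixture with weights of 0.502 and 0.458, but the pit-like cluster alone had 0.863 times, so the spread cannot tell a mixture from 1 population. Cym, a chief cell gene, was at 6.19 times the higher of both clusters (993 against 160 CPM). It cannot decide about that mixture for the cluster as a whole, because 33 of 1084 cells had a Cym UMI and 10 cells held 91.3% of the Cym UMIs. The best marker class of cluster 11 was squamous forestomach, with a score of 2.23 against 1.43 for proliferating. Of its markers, 4 were higher than elsewhere, 1 was among the 50 leading genes and 0 among the first 10. Squamous cells and a distinct injured cell state stay open and were not tested.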

How the results depend on the processing

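Alternatives chosen after seeing the data were the named denominator, removal of the highest Scrublet scores, the deepest 1% left out, and list medians without abundant genes. No paired analysis was possible because each group has 1 library and the groups share only replicate number 1. Values are log2 ratios in the order day 1 to untreated, day 3 to day 1 and AREG to day 3, as far as they left the counting interval. Within it stayed 24 values of Areg, 15 of the parietal-like, 12 of the pit-like and 7 of the proliferating-like share. The counts of lists outside the central 95% stayed within 1.5 times in all 9 cases, and of the list medians 158 moved by under 0.25 and 49 by more; none outside the central 95% took the other sign. Direction was lost for the pit-like share to untreated with named cells as denominator (0.21) and with at least 1000 UMIs (0.36), where unnamed day 1 cells were left out or came to 9.19%. Leiden resolution 0.5 turned the proliferating-like share to -2.75 and 0.27 and moved the pit-like share to -3.02, 3.86 and -0.20; 81.7% of day 1 epithelial cells were then unnamed, but 0.364% and 0.256% in the libraries of the last value, and the cause was not tested. Equal weight per cell turned Areg with AREG to -0.020 and moved its day 3 value to -3.56. Areg was 2.46 and -2.72 with a pseudocount of 10 CPM, 3.21 at day 1 without the abundant genes and -3.85 at day 3 without the deepest 1%. With named cells as denominator the parietal-like share was -1.45 and 1.14, the proliferating-like share 2.34 and -3.93, and the pit-like share 0.45 at day 3. With at least 1000 UMIs the parietal-like share was -1.72, 1.42 and 0.12, the proliferating-like share 1.57, -2.88 and 0.79, and the pit-like share 0.42 and -0.42 in the later comparisons. At most 20% mitochondrial UMIs gave a parietal-like share of -4.00 and 3.69, a proliferating-like share of 0.91 and -2.70, and a pit-like share of -0.40 with AREG. No mitochondrial limit gave a parietal-like share of -1.67 and 1.30, a proliferating-like share of 1.14 and a pit-like share of -0.10 at day 1. Doublets kept gave a proliferating-like share of 1.71 at day 1. Leiden resolution 2 gave proliferating-like shares of 1.66, -2.37 and 0.92. Removal of the highest Scrublet scores gave proliferating-like shares of 1.11, -2.91 and 0.99, and pit-like shares of -0.039 and 0.68. Where no construction is named, the cause was not tested. Few cells limit the day 1 neck-like and chief-like values, from 79 and 6 cells, and few UMIs limit scarce genes such as H2-Aa, with 8 against 2.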

Other observations

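The tests of explanations in this part were all chosen after the result they bear on was seen. Day 3 against untreated, the side comparison, had an all-gene median log2 ratio of 0.36. Against it ERBB receptors and regulators had a median of 1.18, with Erbb2 at 36.3 against 15.1 CPM and Erbb3 at 46.9 against 20.6, and hedgehog, BMP and Wnt signals 0.94. Cluster 16, the pit-like cells led by Isg15, Oasl2 and Ifit1, was 0.710% of epithelial cells in the untreated library, 0 of 3738 cells at day 1 (upper 95% bound 0.0986%), 4.17% at day 3 and 1.28% with AREG. Endocrine-like cells, led by Chga and Hdc, were 2.84%, 0.936%, 0.653% and 1.03% in the same order, and tuft-like cells, led by Alox5ap and Rgs13, were 0.884%, 1.36%, 0.213% and 0.326%. Cluster 24, led by the intestinal genes Prap1, S100g and Apoa4, had 38 untreated and 5 day 1 cells. Sltm, an RNA-binding protein gene chosen after its values were seen, was at 152, 227, 1236 and 1323 CPM, apart from both earlier libraries in both day 3 libraries.

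Lower Gkn3 and Muc6 in neck-like cells of the AREG library had several candidate explanations. Pit-like cells mixed into the class are argued against, since their Tff1 implied a pit-like share of UMIs of 5.26% and the Gkn3 difference needed 68.4%. The share of 5.26% was computed from the Tff1 difference itself, so mixing stays open for the higher Tff1. Mixing was not tested for Muc5ac. A few deep cells are argued against, since with equal weight per cell the log2 ratio of Gkn3 was -1.34 and that of Muc6 -1.42. Of 2394 neck-like cells with AREG 40.9% had a Gkn3 UMI, against 59.3% of 971 without. For Muc6 these shares were 50.5% and 71.4%, at median UMIs of 2313 and 2646. The lower levels thus went with more cells without a UMI of these genes in a larger class. Entry of cells other than pit-like ones into the class was not tested. A difference between the 2 libraries other than AREG stays open, because Muc6 at day 3 was 5.27 times its untreated level (1862 against 353 CPM) and Gkn3 was at 4153 against 1247 CPM. That comparison crosses clusters, since 96.3% of untreated neck-like cells lay in cluster 8 and 94.4% of day 3 ones in cluster 3, and Muc6 was at 1669 CPM in day 1 neck-like cells. AREG acting on neck cells stays open as well, and 1 library per group leaves these explanations such that they cannot be told apart.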
